A study of Rattus norvegicus with 30 samples.

How the data were processed

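Amygdala RNA from 30 adult rats was measured on Illumina BeadChips, with 5 female and 5 male rats in each of 3 conditions. Per the labels' protocols, the tissue was dissected on dry ice and kept in RNAlater, RNA was isolated on RNeasy columns with DNase treatment, and biotin-labelled cRNA was made with the Illumina TotalPrep kit. Groups, sexes and replicate numbers were taken from the sample labels, which name a separate rat for each array.

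The values used were the log2 intensities deposited by the authors for 22523 probes. The log2 scale was judged from their range (6.38 to 15.06). The columns share the same median (7.02) and quartiles, as after quantile normalization over all arrays, and genes were not centred. The software, the background correction and the normalization tool are not given in the sources used here. Another deposited table with 30 signal and 30 detection p-value columns was not used, because its 60 column names match no sample. The planned test on background-corrected scanner values was therefore replaced by the same limma fit on the authors' log2 values, and the planned filter on detection p by a filter on intensity.

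Of the probes, 13793 carried 1 gene symbol, 0 carried several and 8730 carried none. Gene identifiers of 13752 probes matched the RefSeq gene table of the GRCr8 assembly, and 0 symbols changed. A probe was tested when it was above the array median on at least 5 arrays, which left 13309 probes, 9359 named and 3950 unnamed. The named probes stand for 9166 genes, of which 184 had several probes. The lowest and highest correlations between 2 arrays were 0.9559 and 0.9953, and 0 pairs of columns were identical. Of 11 Y-linked gene symbols looked up 0 were found among the named probes, so the sex labels were not checked with them.

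Group means of the 6 groups were fitted to each probe with limma 3.58.1 in R 4.3.3, with 24 residual degrees of freedom. From this fit 13 comparisons were made, and p values were adjusted by the method of Benjamini and Hochberg over all probes of a comparison, with a threshold of 0.05. Of 39 gene lists, 36 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry served as alternatives. Counts adjusted over the list alone apply the same adjustment to the members of a list.

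Named genes were chosen by rule: the 12 largest changes each way among the calls in exposed minus control and in extreme minus minimal within a sex, 10 each way for male minus female and 4 each way for the others. Where fewer than 10 passed in one of the first 4, genes with the smallest p were added. Up to 4 members of each described list with the smallest p were added, and Nr3c1, Nr3c2, Fkbp5, Sgk1 and Tsc22d3 in every comparison within a sex. Not every gene chosen in this way is printed for every comparison. For a gene with several probes the probe with the highest mean was used. On simulated data for female extreme minus minimal with 13309 probes, 96% of 100 probes changed by a log2 of 1 were recovered. Of 100 probes changed by 0.5, 70% were recovered. There were 2 false calls, and an unchanged comparison gave 0 calls. The simulated noise was drawn independently for each probe and array, so it does not give the rate of false calls in the real data. With group labels redrawn among the real arrays of that comparison, up to 1347 probes passed.

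The groups, comparisons, gene lists, rule for named genes and the first set of other settings were chosen before the data were examined. Those settings that could be run were no filter, array weights, robust variances with an intensity trend, the replicate number as a block, 1 probe per gene, only the arrays of the sex compared, and leaving out each array in turn. Added after the data were seen were the array state and 3 regional scores as covariates, alone and together, arrays of a single state, a filter at the 60th percentile (7.2) on 15 arrays, which left 8902 probes, and a normexp background correction with an offset of 16. The array state was found by searching for probes that part the arrays with a gap of at least 1, with at least 5 arrays on each side. Unchanged female groups with shared controls, without and with correlated same-numbered pairs, were simulated 100 times each. Group labels were also redrawn in 100 regroupings per comparison.

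Deviations of same-numbered arrays from their group means correlated between female minimal and female extreme at 0.146 to 0.687 (mean 0.421, against -0.104 for other numbers), and 4 of 5 arrays matched best with their own number. As every pair was above 0.1, these 2 groups were regarded as paired by number. The reported fits, SEs and list tests do not use the pairing. Values with the replicate number as a block shared by all 6 groups are given where they change a call. Same-numbered arrays correlated at -0.172 and -0.322 on average between female control and female minimal and extreme, so this block does not isolate the pairing. A block over the exposed females alone was fitted only for the count of calls. No label says what the numbers share, and no other pair of groups met the rule. In both groups the mean of the myelin genes, relative to all arrays, was higher in numbers 1 to 3 than in 4 and 5. It was 1.12, 1.39, 1.24, -0.382 and -0.243 in female minimal 1 to 5. In female extreme 1 to 5 it was 1.65, 1.08, 0.958, -0.222 and 0.131. The shared numbers may thus reflect tissue composition, which was not tested.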

Results

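Transcript levels were measured with Illumina BeadChips in the amygdala of 30 adult Sprague Dawley rats, on 1 array per rat. Some rats had smelled a predator and were afterwards classed by how strongly their behaviour changed, as extreme or minimal responders. The others had no scent exposure and served as controls. With both sexes this made 6 groups of 5 rats, and the labels give each array a rat identifier of its own, so the replicates were separate animals. Of 22523 probes, 13309 passed the intensity filter, and 9359 of these carried a gene symbol. The number of arrays limits the precision of every value. Unless another error is named, values are log2 fold changes ± the standard error (SE) of 1 fit over all 30 arrays, with 10 exposed against 5 control rats or 5 against 5 rats of single groups within a sex.

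A property of the arrays cut across the groups and is given beside the comparisons that it touches. A set of 8 probes, among them the probes of the ribosomal protein genes Rpl37l1, Rpl7 and Rpl23, placed 14 arrays in a lower and 16 in a higher state, with gaps of 1.02 to 3.55 between the states. The Rpl37l1 probe read 9.62 ± 0.27 (SD, n = 14) in the lower and 12.45 ± 0.18 (SD, n = 16) in the higher state. The 3 probes of the cytoskeletal gene Actb ran the other way, by -1.07, -1.34 and -0.53 within groups. All 5 female control and all 5 male extreme arrays were in the lower state, with female minimal 2 and 3, female extreme 2 and male minimal 1. All 5 male control arrays were in the higher state. Within groups that held both states, 1170 probes differed between the states by limma, 520 higher and 650 lower in the higher state. In these groups only female minimal 2 and 3, female extreme 2 and male minimal 1 were in the lower state. The myelin mean was 1.39 and 1.24 in female minimal 2 and 3, against 1.12, -0.382 and -0.243 in female minimal 1, 4 and 5. The state difference may thus hold some of the tissue composition.

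The first question was how exposure to predator scent related to transcript levels in female rats. Among 18 measured genes known to be induced by glucocorticoids, 4 rose in exposed females and 0 fell over all probes, and 5 rose and 1 fell when adjusted over the list alone. The glucocorticoid-regulated kinase Sgk1 rose by 0.99 ± 0.23, Ddit4, an inhibitor of mTOR signalling, by 0.74 ± 0.15, Errfi1, an inhibitor of the EGF receptor, by 0.65 ± 0.13, and Tsc22d3, which encodes the protein GILZ, by 0.42 ± 0.11. The glucocorticoid receptor gene Nr3c1 was at 0.04 ± 0.07, the mineralocorticoid receptor gene Nr3c2 at 0.12 ± 0.11 and the receptor co-chaperone gene Fkbp5 at -0.25 ± 0.25, and these did not pass. In the receptor complex list, 1 of 13 genes rose and 1 fell, over all probes and adjusted over the list alone. The chaperone gene Hsp90aa1 rose by 0.56 ± 0.14 and the co-repressor gene Ncor1 fell by 0.41 ± 0.11. Of the clock genes, 3 of 13 fell, or 4 adjusted over the list alone. Npas2 fell by 0.41 ± 0.08, Nr1d1 by 0.44 ± 0.12 and Bhlhe40 by 0.75 ± 0.23.

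Of 13 heat shock chaperones 2 rose, over all probes and adjusted over the list alone, namely Hsp90aa1 and the mitochondrial chaperonin gene Hspe1 (0.67 ± 0.19). Of 16 genes of endoplasmic reticulum stress 1 rose, or 2 adjusted over the list alone, led by the disulfide isomerase gene Pdia3 (0.67 ± 0.13). The strongest rises outside the lists included Scg2, the precursor of the peptide secretoneurin, at 1.08 ± 0.23, the glycerol-3-phosphate dehydrogenase gene Gpd1 at 1.06 ± 0.25, and the deacetylase gene Sirt2 at 0.80 ± 0.16. Among the strongest falls were Lamp5 at -1.58 ± 0.40, the AMPA receptor auxiliary subunit gene Cacng3 at -1.02 ± 0.29, the transcription factor gene Klf5 at -1.02 ± 0.18, the active zone gene Rims1 at -0.87 ± 0.17 and the kinase gene Camk2a at -0.80 ± 0.23. Lamp5 and Camk2a were the 2 of 10 excitatory neuron markers that fell, over all probes and adjusted over the list alone. Of 61 ribosomal protein genes 10 rose and 2 fell, or 14 and 5 adjusted over the list alone, with Rpl24 at 0.45 ± 0.08, Rpl14 at 0.33 ± 0.06 and Rpl10 at -0.33 ± 0.06. The 3 ribosomal probes that mark the array state had the values 1.75 ± 0.53 for Rpl37l1, 1.40 ± 0.43 for Rpl7 and 1.02 ± 0.29 for Rpl23, and turned to -0.32, -0.23 and -0.08 with the state as a covariate. Of 20 oligodendrocyte and myelin genes 0 passed over all probes or adjusted over the list alone, with a median of 0.54. Mal, a myelin proteolipid gene, was at 1.10 ± 0.47. The control group was itself split by the myelin mean relative to all arrays. It was -1.01 in both female control 1 and 2, against 0.986, 0.853 and 0.717 in female control 3, 4 and 5. Exposed females ranged from -0.382 to 1.65. No fit took the myelin mean into account, so whether the changes of single genes follow it was not tested. Of 8 blood cell genes 0 passed over all probes and 2 were lower adjusted over the list alone, with a median of -0.25. The haemoglobin gene Hbb-b1 was at -0.80 ± 0.27. No member passed in the stress neuropeptide list (0 of 10; Avp at 1.03 ± 0.55) or among the immediate early genes (0 of 15; Nr4a2 at 0.42 ± 0.19), over all probes or adjusted over the list alone.

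In all, 918 probes passed in limma, 435 higher and 483 lower in exposed females, where 665 of 13309 probes would have an unadjusted p under the same threshold by chance and 2742 did. Camera placed 7 lists past the threshold. These were the glucocorticoid-induced genes (adjusted p = 0.0267; adjusted p = 0.539 with an estimated correlation), clock genes (0.0267; adjusted p = 0.356 with an estimated correlation), endoplasmic reticulum stress genes (0.0244; adjusted p = 0.713 with an estimated correlation) and heat shock chaperones (0.0471; adjusted p = 0.745 with an estimated correlation). The myelin (0.000882), ribosomal (0.0471) and blood (0.0471) lists each had an adjusted p = 0.891 with an estimated correlation. By fry only the glucocorticoid (adjusted p = 0.0338) and clock (adjusted p = 0.00368) lists of these passed. With the replicate number as a block 4 lists passed, and the blood, ribosomal and heat shock lists were at 0.0566. With the array state as a covariate 646 probes passed, 343 of them among the 918, and 99% of the 918 kept their sign (median size 0.357 before and 0.305 after, median SE 0.0886 and 0.107). Within the lower-state arrays, 3 exposed against 5 control rats, 328 probes passed. The count was 390 without female control 2 and 591 without female control 1. Of the 37 named genes that passed, 21 lost their limma call without female control 2, Sgk1 (adjusted p = 0.0552) and Lamp5 (0.0593) among them. The SE pools the spread of both sexes, and females varied more, with an SD of the myelin mean of 0.868 against 0.392 in males. In a limma fit of the female arrays alone 23 of the 37 named calls ended. Leaving out 1 array ended 6 of the 7 list calls, from 2 of 15 arrays for the endoplasmic reticulum stress and myelin lists, and 3 for the glucocorticoid list, to 9 for the chaperone and ribosomal lists, and ended no call of the clock list.

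The second question was what set extreme responders apart from minimal ones among exposed females. The transcription factor gene Nfil3 was higher by 1.05 ± 0.14 in extreme females, the stress-response gene Gadd45g by 0.99 ± 0.16. Also higher were Nfkbia, which encodes the inhibitor IκBα of NF-κB, by 0.96 ± 0.17, and Apold1, an endothelial early response gene, by 0.78 ± 0.09. Higher as well were Tmem252 (0.70 ± 0.13), the protocadherin gene Pcdhgc3 (0.38 ± 0.08), the stress-induced transcription factor gene Atf3 (0.38 ± 0.07) and the hyaluronidase gene Hyal2 (0.35 ± 0.06). Lower in extreme females were Ndrg2, a gene of astrocytes, at -0.61 ± 0.09, the phosphoglucomutase gene Pgm1 at -0.57 ± 0.12, Poldip2 at -0.54 ± 0.07, Borcs7 at -0.51 ± 0.09, the prolyl hydroxylase gene P4ha1 at -0.45 ± 0.08, Pomgnt1 at -0.43 ± 0.09 and the coenzyme Q gene Coq9 at -0.42 ± 0.07, whose other probe was at -0.01. Nfil3 averaged 9.24 ± 0.31 (SD, n = 5) in extreme, 8.20 ± 0.19 in minimal and 8.20 ± 0.23 in control females, and 8.03 ± 0.08 to 8.24 ± 0.26 in the male groups.

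**Figure D1:**
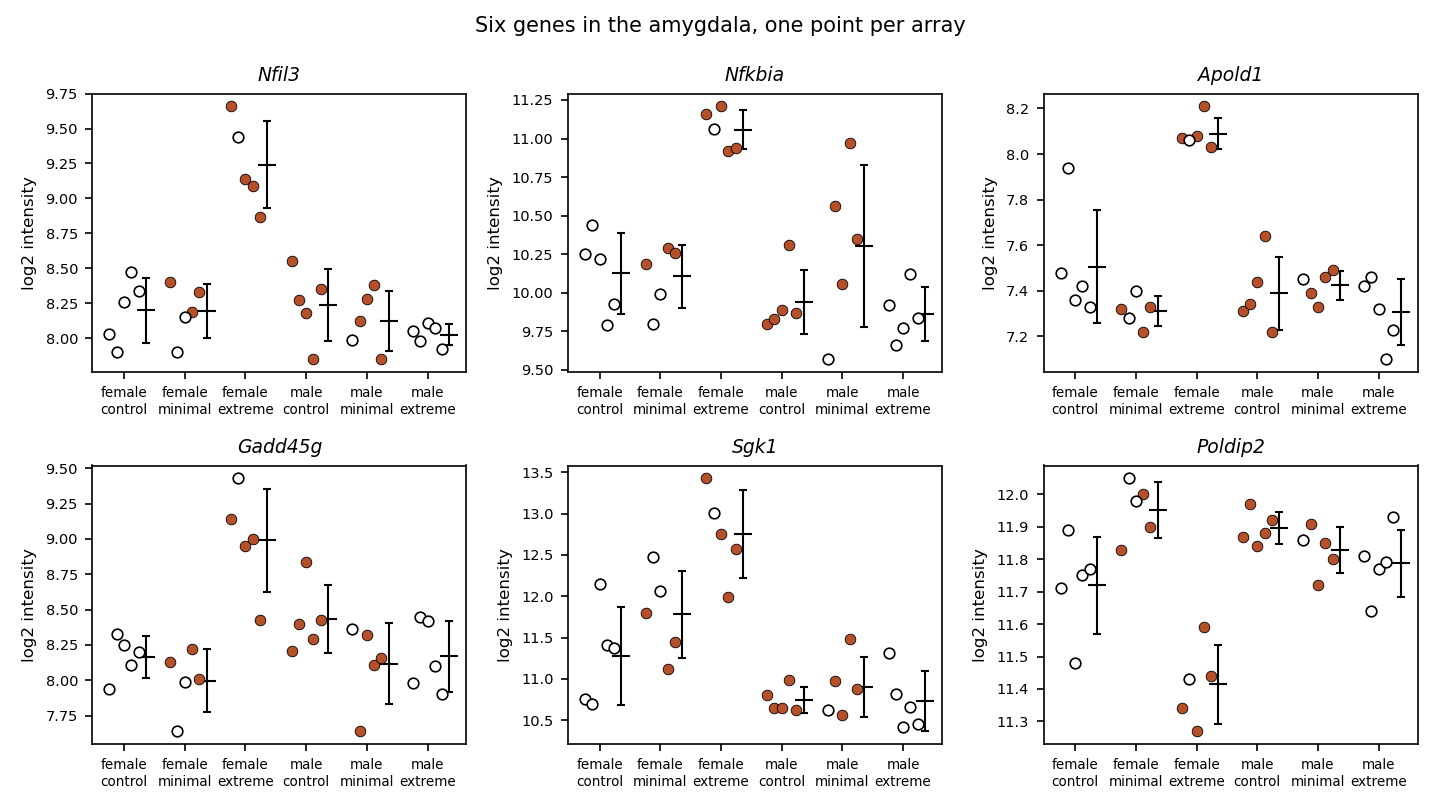
Log2 intensity (vertical axes) of 6 genes in the 6 groups of 5 arrays (horizontal axes), where each point is an array, filled for the higher and open for the lower array state, and bars give the mean ± SD. The 5 female extreme arrays lie above all other arrays for Nfil3 and Apold1, and below all female minimal arrays for Poldip2.

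For each of these 15 genes the 5 extreme arrays did not overlap the 5 minimal arrays, which for a single gene and direction happens by chance in 0.397% of splits. The genes were picked for their difference, so this describes them and tests nothing further. The values of Nfil3, Apold1 and Hyal2 in extreme females lay above those of all other arrays. Of the glucocorticoid-induced genes, 2 of 18 rose over all probes (Gadd45g and Nfkbia) and 7 adjusted over the list alone, and 13 were positive, while Dusp1, a phosphatase gene, was at 1.21 ± 0.33 and Sgk1 at 0.97 ± 0.27. The mean of the list differed by 0.308 ± 0.0654 (5 against 5 rats). With the rats paired by number, all 5 differences were positive (0.181 to 0.478, with a two-sided exact permutation p = 0.0625, the smallest that 5 pairs can give). Without the pairing the two-sided exact permutation p was 0.00794. Within the higher-state arrays the difference was 0.243 ± 0.0811 (4 against 3 rats; two-sided exact permutation p = 0.0286 without the pairing). No receptor complex gene (0 of 13; Nr3c1 at 0.09 ± 0.08, Nr3c2 at -0.07 ± 0.13, Fkbp5 at -0.46 ± 0.29) and no stress neuropeptide gene (0 of 10; Crh at 0.29 ± 0.19, Oxt at -0.92 ± 0.49) passed, over all probes or adjusted over the list alone. Of 15 immediate early genes 0 passed over all probes and 4 were higher adjusted over the list alone, with Ier2 at 0.61 ± 0.14, Fos at 1.01 ± 0.29, Klf4 at 0.62 ± 0.17 and Klf2 at 0.57 ± 0.15. Of 70 genes of oxidative phosphorylation 0 passed over all probes or adjusted over the list alone, with 58 positive and a median of 0.10 (adjusted p = 0.539 with an estimated correlation). Of 14 astrocyte markers 0 passed over all probes, while 1 was higher and 1 lower adjusted over the list alone, with a median of -0.24 (adjusted p = 0.388 with an estimated correlation). The glutamate transporter gene Slc1a3 was at -0.41 ± 0.13.

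For markers of neighbouring brain regions in the same comparison, the median was -0.38 for 17 striatal and central amygdala markers, 0.38 for 12 thalamic markers, -0.27 for 12 hypothalamic markers and -0.17 for 7 cortical markers. None of these passed over all probes, and 1 cortical marker was lower adjusted over the list alone. Of 15 inflammatory genes 1 rose over all probes, Nfkbia, and 2 adjusted over the list alone; of 26 antigen presentation genes 0 passed either way, with a median of -0.10. The preset camera test placed 10 lists past the threshold, and the glucocorticoid list alone stayed past it with an estimated correlation (adjusted p = 3.83e-05; adjusted p = 0.0493 with an estimated correlation). The immediate early list (3.83e-05) had adjusted p = 0.334 with an estimated correlation, oxidative phosphorylation (3.83e-05) 0.539, and the astrocyte (0.00437), cortical (0.0152) and antigen presentation (0.00931) lists adjusted p = 0.388 with an estimated correlation. The inflammatory (0.0467), hypothalamic (0.0467), thalamic (0.0467) and striatal (0.0467) lists had adjusted p = 0.389, 0.539, 0.691 and 0.748 with an estimated correlation. With the replicate number as a block the hypothalamic (0.0516), inflammatory (0.0607) and thalamic (0.0624) lists and Pcdhgc3 (0.0678) missed the threshold. Leaving out 1 array ended no call of the glucocorticoid, immediate early, oxidative phosphorylation and astrocyte lists, while the thalamic list went to 0.753 without female extreme 2 and the striatal list to 0.364 without female minimal 1.

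By limma without the pairing 17 probes passed between extreme and minimal females, 9 higher and 8 lower, 15 of them named. The count was 29 without female extreme 4, 26 without female extreme 5, 26 with the array state and 11 with 3 regional marker scores as covariates (median size 0.538 before, 0.514 and 0.502 after). With array weights the count was 10, and 7 of the 15 named limma calls ended, Nfkbia (0.908, adjusted p = 0.0886) and Hyal2 (0.328, 0.0886) among them. In a fit of the female arrays alone 7 probes passed and 8 of the 15 calls ended. Within the lower-state arrays 5 probes passed, where the lone extreme array was assumed to vary like the other groups. Within the higher-state arrays 5 passed (4 against 3 rats) and 13 of the 15 calls ended. In that limma fit Apold1 (0.81) and Poldip2 (-0.50) kept their calls, and Nfil3 was at 0.885 (adjusted p = 0.22) and Nfkbia at 0.815 (0.246). A fit of the 10 exposed females alone gave 3 calls, and 2 with the replicate number as a block. Of the 15 named genes, 5 lost their call when some array was left out, all 5 of them without female extreme 3 (Pomgnt1 to 0.175, Pcdhgc3 to 0.124, Pgm1 to 0.12, Atf3 and Tmem252 to 0.0641).

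The extreme and minimal groups were also set against female controls separately. In extreme females 7 of 18 glucocorticoid-induced genes rose and 1 fell, over all probes and adjusted over the list alone, with Sgk1 at 1.47 ± 0.27, Ddit4 at 0.99 ± 0.17, Nfkbia at 0.94 ± 0.17 and Errfi1 at 0.93 ± 0.15. In minimal females 0 of the 18 passed by either adjustment, and Sgk1 was at 0.50 ± 0.27 and Ddit4 at 0.49 ± 0.17. Of the immediate early genes, 1 of 15 rose in extreme females, Ier2 (0.47 ± 0.14), and 3 adjusted over the list alone. Of the astrocyte markers, 2 of 14 fell by either adjustment, Mlc1 (-0.98 ± 0.24) and Cldn10 (-0.32 ± 0.09). Of the clock genes, 2 of 13 fell in minimal females, Nr1d1 (-0.68 ± 0.14) and Npas2 (-0.41 ± 0.10), or 3 adjusted over the list alone, and 1 in extreme females, Npas2 (-0.42 ± 0.10), or 2 adjusted over the list alone. Other strong changes were Ttr, the choroid plexus gene of transthyretin, at 2.79 ± 0.80, Lamp5 at -1.82 ± 0.46 and Ephx4 at -1.53 ± 0.41 in extreme females. In minimal females they were the cyclic AMP sensor gene Rapgef3 at 0.73 ± 0.15, Taf9b at 0.71 ± 0.13, Pdia3 at 0.68 ± 0.15, Klf5 at -1.03 ± 0.21 and the proteoglycan gene Cspg5 at -0.80 ± 0.11, whose other probe was at -0.63. The mean of the choroid plexus markers was 0.016 ± 0.224 (SD, n = 5) in control, 0.215 ± 0.338 in minimal and 0.455 ± 0.538 in extreme females, with female minimal 5 at 0.752 and female extreme 3 at 1.36. Of 18 named limma calls in extreme females 10 ended without female extreme 3, among them Ttr (adjusted p = 0.127), Lamp5 (0.0674), Ephx4 (0.0928), Ier2 and Cldn10. The call of Ier2 ended with 6 of 10 left-out arrays and that of Cldn10 with 4. In minimal females 6 of 13 named calls ended without female control 2, Npas2 and Pdia3 among them. A limma fit of the female arrays alone ended 11 of the 18 named calls in extreme and 8 of the 13 in minimal females. In minimal females the hypothalamic markers had a median of 0.39 (0 of 12 past over all probes, 2 higher adjusted over the list alone), and Pmch, a lateral hypothalamic peptide gene, was at 2.88 ± 0.92.

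In extreme females 870 probes passed (446 higher, 424 lower) and in minimal females 264 (110 higher, 154 lower). With an estimated correlation no list remained past the threshold in either comparison, and for the glucocorticoid list in extreme females the preset adjusted p was 0.00125 (adjusted p = 0.133 with an estimated correlation). Of the lists past camera, fry kept the glucocorticoid (adjusted p = 0.000685) and clock (adjusted p = 0.00707) lists in extreme females. In minimal females it kept only the clock list (adjusted p = 0.0205). The clock list had 0.0399 in extreme (adjusted p = 0.314 with an estimated correlation) and 0.0288 in minimal females (adjusted p = 0.422 with an estimated correlation). In extreme females the immediate early and astrocyte lists both had 0.0114 (adjusted p = 0.787 and adjusted p = 0.767 with an estimated correlation). In minimal females the hypothalamic list had 0.0128 (adjusted p = 0.506 with an estimated correlation). The myelin list had 0.00135 in extreme (median 0.575; adjusted p = 0.787 with an estimated correlation) and 0.00269 in minimal females (median 0.502; adjusted p = 0.978 with an estimated correlation), with 0 of 20 past over all probes. In minimal females the blood (0.0189) and heat shock (0.0422) lists had adjusted p = 0.506, the ribosomal list (0.0279) adjusted p = 0.978 and the endoplasmic reticulum stress list (0.00269) adjusted p = 0.422 with an estimated correlation. The 870 calls became 481 without female control 2 and 506 without female extreme 3. The 264 calls became 145 without female minimal 1, 148 without female control 2, 165 without female control 4 and 430 without female minimal 2. Leaving out 1 array ended no call of the glucocorticoid and astrocyte lists in extreme females, while the immediate early list went to 0.189 without female extreme 4. The clock call ended with 3 of 10 left-out arrays (up to 0.0623) and the myelin call with 2 (up to 0.0706). In minimal females all list calls but endoplasmic reticulum stress ended without some array, the ribosomal list in 7 of 10 cases and the clock list in 6. Within the lower-state arrays, 134 probes passed for extreme females, where the lone extreme array was assumed to vary like the other groups, and 39 for minimal females (2 against 5 rats). Both comparisons used the same controls: 187 probes passed in both in the same direction, 86 higher and 101 lower, against 3.69 and 4.91 for independent lists of these sizes, which leave out the shared controls. In 100 simulations of unchanged groups with shared controls 0.2 probes on average (at most 2) passed in both, and the equally many probes with the smallest p shared 92.5 on average (at most 117). Their fold changes correlated across probes at 0.74, and at 0.39 on average over 20 splits of the controls (0.0607 to 0.571), with a covariance of 0.0346. Simulated unchanged groups gave a correlation of 0.5 and a covariance of 0.0138 with shared controls alone. With same-numbered rats also correlated at 0.421, as measured, they gave 0.711 (0.684 to 0.741), 0.137 over splits of the controls, a covariance of 0.0197 (0.0178 to 0.0218) and 156 shared probes of smallest p (131 to 172). The observed correlation lies within the paired range, so by itself it does not show a shared effect. The covariance lies above its paired range, as does the mean over splits of the controls (0.39 against 0.0971 to 0.185). The 187 shared calls also exceed the paired simulations, with at most 5 called in both and at most 172 by smallest p. The simulated probes were independent of each other, which makes these ranges too narrow.

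In male rats exposure was compared with control in the same way. Of the 18 glucocorticoid-induced genes 0 passed over all probes or adjusted over the list alone. Sgk1 was at 0.08 ± 0.23, Tsc22d3 at -0.03 ± 0.11, Nr3c1 at -0.10 ± 0.07, Nr3c2 at 0.00 ± 0.11 and Fkbp5 at -0.09 ± 0.25. The receptor complex (0 of 13), stress neuropeptide (0 of 10; Avp at -0.79 ± 0.55) and immediate early (0 of 15; Arc at 0.34 ± 0.35) lists had no member past either adjustment. Ribosomal protein genes had a median of -0.07 (0 of 61 past over all probes, 7 lower adjusted over the list alone), with Rpl23a at -0.32 ± 0.07. The genes with the smallest p were the cilia gene Bbs4 at 0.50 ± 0.09, the nucleolar gene Nop58 at -0.43 ± 0.08, the synaptic vesicle gene Sv2b at 0.76 ± 0.15 and the endoplasmic reticulum chaperone gene Hsp90b1 at 0.38 ± 0.09. By limma 0 probes passed (smallest adjusted p 0.0612), with 1247 at an unadjusted p under the threshold where chance gives 665. The count was 193 with array weights, 53 in a fit of the male arrays alone, 6 with regional scores as covariates, and 3, 2 and 1 without male extreme 1, male extreme 2 and male control 4. Camera gave the ribosomal list an adjusted p of 0.00734 (adjusted p = 0.964 with an estimated correlation), and 0.625 without male control 3.

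Extreme and minimal males differed at 0 probes by limma (smallest adjusted p 0.101; 1331 at an unadjusted p under the threshold). The largest evidence lay with Tssc4 at -0.32 ± 0.06, the RNA methylation reader gene Ythdc1 at 0.36 ± 0.07, the mitochondrial helicase gene Twnk at 0.43 ± 0.09, the growth factor gene Ptn at -0.63 ± 0.13, Sgca at -0.65 ± 0.14 and Neurl2 at -0.48 ± 0.10, whose other probe was at 0.06. No glucocorticoid-induced (0 of 18; Nfkbia at -0.44 ± 0.17, Sgk1 at -0.17 ± 0.27), receptor complex (0 of 13; Stip1 at 0.19 ± 0.12), stress neuropeptide (0 of 10; Crh at -0.20 ± 0.19) or immediate early gene (0 of 15; Ier3 at -0.31 ± 0.13) passed over all probes or adjusted over the list alone, and 0 lists passed. The count became 51 without male minimal 1, the only array of its group in the lower state, 201 with array weights and 76 in a fit of the male arrays alone.

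Extreme males differed from male controls at 106 probes, 40 higher and 66 lower. The sulfotransferase gene Gal3st3 rose by 0.88 ± 0.18, Sv2b by 0.76 ± 0.18 and the delta-catenin gene Ctnnd2 by 0.75 ± 0.16, and the chaperonin gene Hspe1 fell by 0.95 ± 0.22. All 9 named limma calls of this comparison ended without male control 1, and the call of Hspe1 ended with 9 of 10 left-out arrays, that of Sv2b with 7. Of 61 ribosomal genes 6 fell over all probes, or 9 fell and 1 rose adjusted over the list alone, with Rpl12 at -0.46 ± 0.09 and the 3 state-marking genes Rpl37l1, Rpl7 and Rpl23 at -2.87 ± 0.61, -2.40 ± 0.50 and -1.58 ± 0.33; the list had an adjusted p of 0.00306 (adjusted p = 0.995 with an estimated correlation), and 0.473 without male control 3. All extreme male arrays were in the lower and all male control arrays in the higher state, so the array state and the group cannot be told apart here. With the state as a covariate, estimated from other groups, 0 probes passed in limma (median size 0.454 before and 0.219 after, median SE 0.103 and 0.12). Without male control 1 to 5 in turn 20, 26, 3, 34 and 38 probes passed, and without male extreme 1, 3, 4 and 5 in turn 52, 55, 36 and 20. Minimal males differed from male controls at 0 probes by limma (smallest adjusted p 0.694; 686 at an unadjusted p under the threshold, 1 call without male control 4, and 2 with array weights), with Sv2b at 0.76 ± 0.18. Meningeal and fibroblast markers had a median of 0.34 in that comparison (0 of 16 past by either adjustment; adjusted p = 0.0039; adjusted p = 0.938 with an estimated correlation; 0.403 without male minimal 2).

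Whether the sexes responded differently was tested as the male minus the female effect. For extreme against minimal responders Nfkbia (-1.40 ± 0.24), Nfil3 (-1.14 ± 0.19) and Apold1 (-0.90 ± 0.13) had lower effects in males, and Phospho2 (0.53 ± 0.10) and Poldip2 (0.49 ± 0.10) higher effects. When 1 array was left out, the Poldip2 call ended in 14 of 20 limma fits (adjusted p up to 0.149) and the Phospho2 call in 8 (up to 0.0908). Both also missed the threshold with array weights, with robust variances and with either covariate. Nfil3 missed it with array weights (-1.05; limma adjusted p = 0.0543). In males alone Nfil3 was at -0.10, Nfkbia at -0.44 and Apold1 at -0.12. The glucocorticoid list passed in this comparison (median -0.23; 1 of 18 lower over all probes, 5 adjusted over the list alone; adjusted p = 0.000422; adjusted p = 0.0838 with an estimated correlation). For the immediate early list (median -0.30; 0 of 15 over all probes, 1 lower adjusted over the list alone) the adjusted p was 0.00394 (adjusted p = 0.463 with an estimated correlation). The astrocyte list had 0.0124 (median 0.403; adjusted p = 0.463 with an estimated correlation), and the striatal (0.0392) and oxidative phosphorylation (0.0183) lists adjusted p = 0.803 with an estimated correlation. By fry only the glucocorticoid list of these passed (adjusted p = 0.00725). No left-out array ended the glucocorticoid call by camera, while the immediate early list went to 0.0583 without female extreme 4. The number of lists past camera, 5 in the full fit, ran from 2 to 8 when 1 array was left out. The limma count was 7 probes, 3 higher and 4 lower. It was 1 with the array state as a covariate, Apold1, where the 7 probes kept their sign with a median size of 0.901 before and 0.921 after and a median SE of 0.129 and 0.157. Nfil3 was then at -1.05 and Nfkbia at -0.987. With regional scores the count was 4. It was 39 without male minimal 1, 31 without female extreme 2 and 16 without female minimal 5. It fell to 4 without female minimal 2 or 4 or male minimal 2, 4 or 5 or male extreme 2 or 3, and 3 without female minimal 3, female extreme 3, male minimal 3 or male extreme 1 or 4.

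For exposed against control rats 597 probes differed between the sexes, 298 with a higher and 299 with a lower effect in males. The GTPase-activating gene Agap2 (1.20 ± 0.28), Gal3st3 (1.19 ± 0.22), the transcription factor gene Zbtb18 (1.19 ± 0.23) and the AMPA receptor gene Gria3 (1.13 ± 0.25) had higher effects in males, and the angiotensinogen gene Agt (-1.82 ± 0.51) and the state-marking Rpl37l1 (-3.47 ± 0.75), Rpl7 (-2.89 ± 0.61) and Rpl23 (-2.01 ± 0.41) lower ones. In the ribosomal list 2 genes had higher and 9 lower effects of 61 over all probes, or 4 and 20 adjusted over the list alone (adjusted p = 0.00375; adjusted p = 0.885 with an estimated correlation), with Rpl12 at -0.56 ± 0.11. The myelin list (0.00621; median -0.664), the blood list (0.036; 1 of 8 higher) and the heat shock list (0.036; 1 of 13 lower) each had adjusted p = 0.885 with an estimated correlation. The array state ran in opposite directions in the sexes, and with it as a covariate 14 probes passed, 7 of them among the 597 (median size 0.518 before and 0.347 after, median SE 0.129 and 0.169). Without female control 2 the myelin, blood and heat shock lists went to 0.117, 0.117 and 0.119, and the limma call of Agt ended (adjusted p = 0.0937). Without female control 2 the count was 293, without male control 3 it was 338, and without female minimal 2 it was 990. Across probes the male and female fold changes correlated at -0.383 for exposed against control, where probes are not independent replicates. With the state as a covariate the correlation was -0.613. That fit removes 1 estimated state effect in opposite directions from the sexes, and error in it pushes the correlation below 0. The value therefore does not show a stronger opposite response.

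Averaged over both sexes, 102 probes changed with exposure, 51 higher and 51 lower, led by the translation factor gene Eif4a1 at 0.43 ± 0.06, with Ddit4 at 0.43 ± 0.10, Pdia3 at 0.40 ± 0.09, Atp13a2 at 0.40 ± 0.09, the neural transcription factor gene Pou3f2 at -0.56 ± 0.11 and Klf5 at -0.56 ± 0.13 (20 exposed and 10 control rats). Of the glucocorticoid-induced genes 1 of 18 rose, or 4 adjusted over the list alone (adjusted p = 0.0272; adjusted p = 0.603 with an estimated correlation), and the myelin list had 0.0272 (adjusted p = 0.983 with an estimated correlation). These 2 list calls ended in 9 and 10 of 30 cases when 1 array was left out, and only Eif4a1 of 8 named genes kept its call in all. With the replicate number as a block the limma call of Ddit4 ended (adjusted p = 0.0562). Without female control 2, 3, 4 and 5 in turn the count was 27, 57, 45 and 47, and without male control 1, 2, 3 and 4 in turn 61, 26, 63 and 50. Between extreme and minimal responders of both sexes 3 probes passed, Borcs7 (-0.37 ± 0.06), Poldip2 (-0.29 ± 0.05) and Tssc4 (-0.23 ± 0.04). The immediate early (0.0122), meningeal (0.0229) and oxidative phosphorylation (0.0106) lists had adjusted p = 0.931 with an estimated correlation. That count was 14 without male minimal 1, 9 without female extreme 5, 8 without female minimal 2 or male extreme 1, 7 without female extreme 1, 6 without female extreme 3, 5 without female extreme 2 or male extreme 4, and 0 by limma with robust variances or with another background correction (1030 probes had an unadjusted p under the threshold in the full fit).

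Male and female rats were compared over all 3 conditions, 15 against 15 rats. Oligodendrocyte and myelin genes were lower in males: 18 of 20 fell over all probes and 19 adjusted over the list alone, with a median of -1.07, Mobp at -1.61 ± 0.37, Cnp at -1.27 ± 0.27 and the glial transcription factor gene Sox10 at -0.90 ± 0.17. Thalamic and habenular markers fell in 8 of 12 (10 adjusted over the list alone), with the glutamate transporter gene Slc17a6 at -2.15 ± 0.44 and Ntng1 at -1.63 ± 0.37. Oligodendrocyte precursor markers fell in 6 of 9 by either adjustment, choroid plexus markers in 4 of 12 (5 adjusted over the list alone; Ttr at -2.80 ± 0.46), and ependymal markers in 4 of 10 (6 adjusted over the list alone). Excitatory neuron markers were higher in males in 5 of 10 (7 adjusted over the list alone), with Fezf2 at 1.13 ± 0.26 and Camk2a at 0.70 ± 0.15. Immediate early genes were higher in 6 of 15 by either adjustment, with Egr1 at 1.14 ± 0.19 and Arc at 1.13 ± 0.23. Of 27 neuropeptide genes 11 rose and 1 fell (11 and 4 adjusted over the list alone), with the peptide gene Cort at 1.07 ± 0.22. Of 17 synaptic vesicle genes 6 rose and 1 fell by either adjustment, with Syn2 at 0.62 ± 0.09 and Sv2b at -0.66 ± 0.10. Of 18 glucocorticoid-induced genes 2 rose and 6 fell by either adjustment, with Sgk1 at -1.14 ± 0.15. Cyp11b1, the gene of the last enzyme of corticosterone synthesis, was higher by 1.48 ± 0.20.

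The mean of the thalamic markers was 0.37 ± 0.66 (SD, n = 15) in females and -0.37 ± 0.11 in males, and that of the myelin genes 0.48 ± 0.87 and -0.48 ± 0.39, so the females varied more. Limma called 2553 probes, 1196 higher and 1357 lower in males. With the thalamic, striatal and hypothalamic scores as covariates 114 probes passed, 84 of them among the 2553 (median size 0.281 before and 0.132 after, median SE 0.0728 and 0.082). Camera placed 10 lists past the threshold, myelin first (7.58e-10), and the immediate early, excitatory, synaptic, thalamic, cortical, myelin, precursor, choroid and neuropeptide lists had an adjusted p = 0.46 with an estimated correlation and the ependymal list 0.485. By fry all 10 passed, with adjusted p from 0.00202 to 0.0227.

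**Figure D2:**
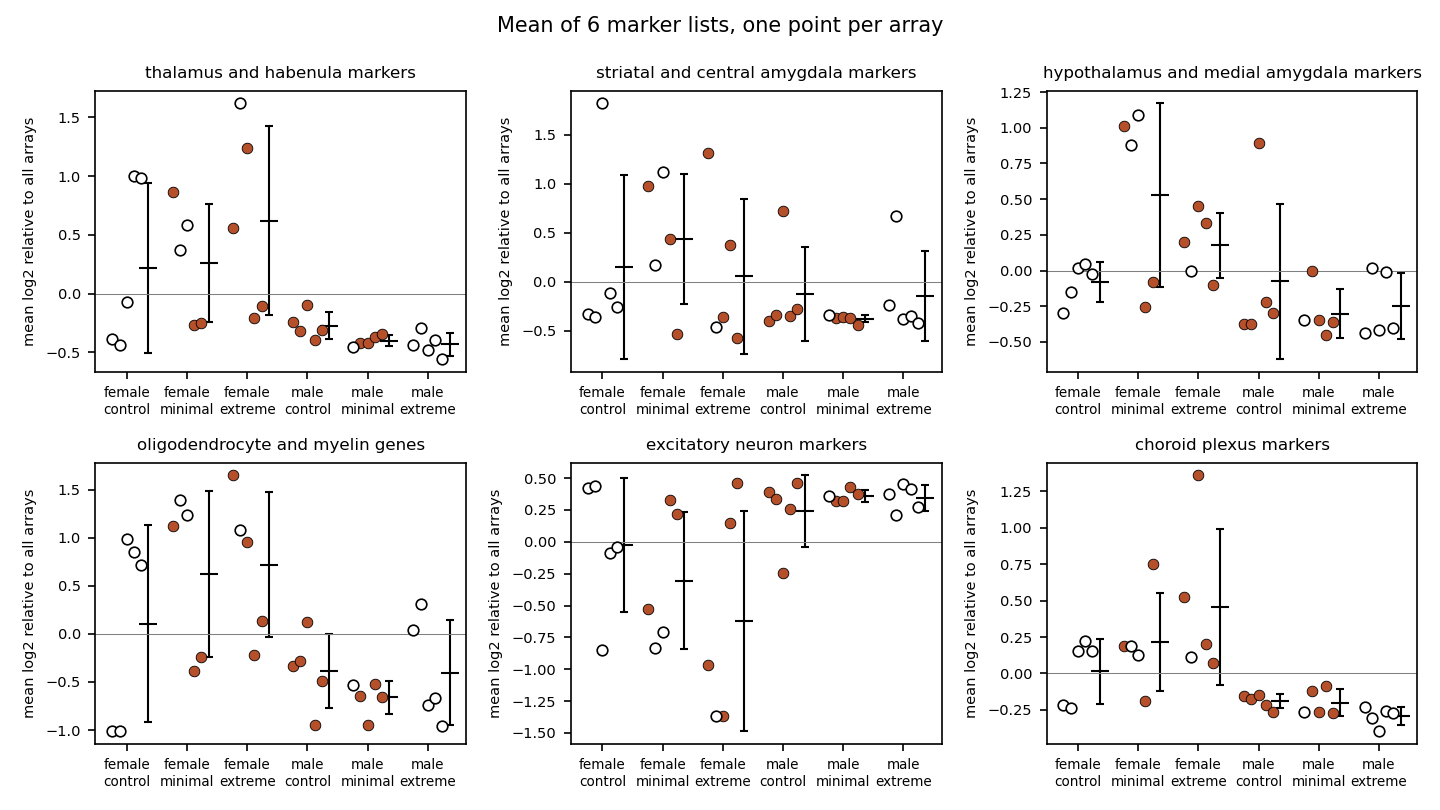
Mean log2 value of 6 marker lists relative to the mean over all arrays (vertical axes) in the 6 groups of 5 arrays (horizontal axes), with filled points for arrays of the higher state, open points for the lower state, and bars for the mean ± SD. The thalamic mean ranges from -0.44 to 1.62 in females and from -0.56 to -0.10 in males.

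**Figure D3:**
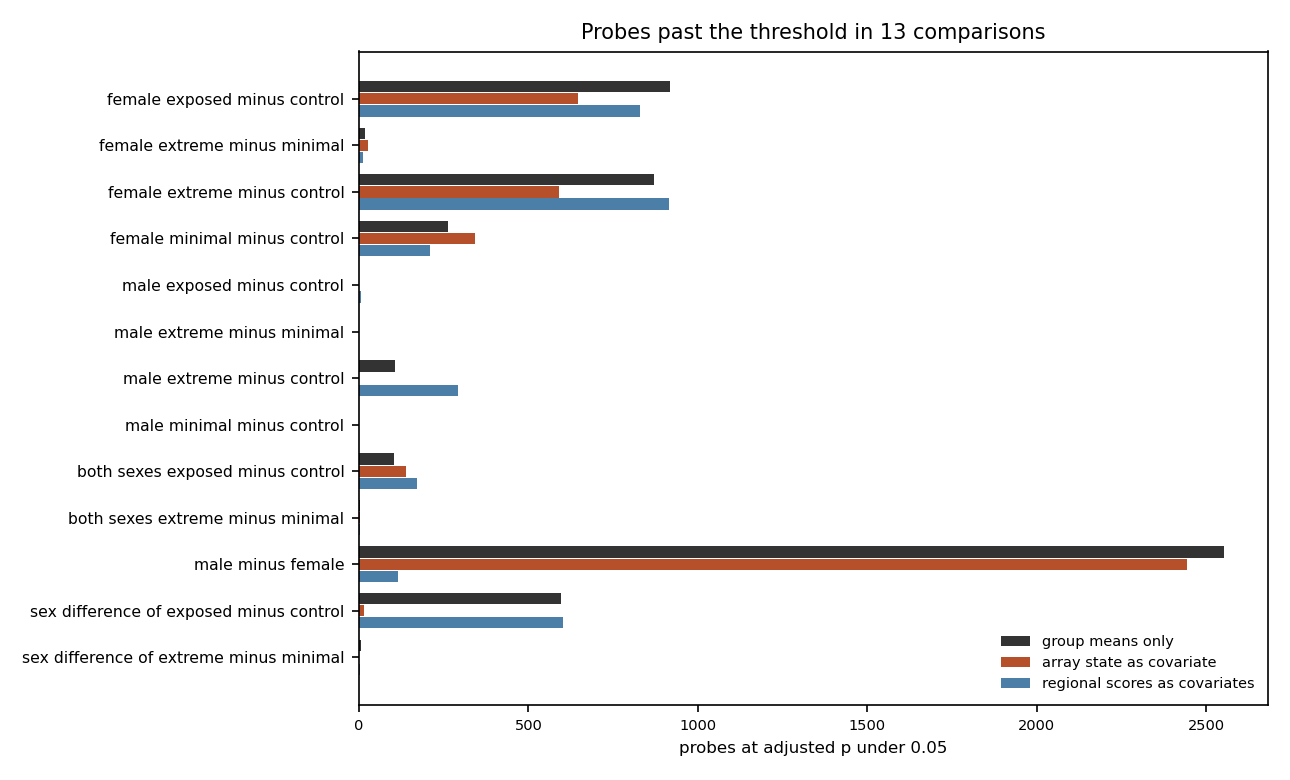
Number of probes past the adjusted threshold (horizontal axis) in each of 13 comparisons (vertical axis), with bars for the fit on group means, with the array state and with 3 regional marker scores as covariates. The count for male minus female goes from 2553 to 114 with the regional scores, and that for the sex difference of exposed minus control from 597 to 14 with the array state.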

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

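All tests in this part were chosen after the results were seen, except the regroupings and the planned settings.

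Within groups of 5, an array was marked when its gap to the nearest other array, as a share of the range of its group, was above 0.71. Chance flags about 1 in 20 groups. Of 216 list values by group 23 (10.6%) were marked, and of 378 gene values 24 (6.35%). Female control 3 stood apart for striatal and central amygdala markers (gap 0.887 of the range; 1.82 against a mean of -0.266 in the others), ribosomal (0.884), GABA receptor (0.843), synaptic vesicle (0.783) and ependymal (0.751) lists. Male control 3 stood apart for striatal (0.891; 0.725 against -0.342), hypothalamic (0.881; 0.89 against -0.317), stress neuropeptide (0.814), hippocampal (0.77) and excitatory (0.714) lists.

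The other marked list values were the receptor complex in female extreme 5 (0.758), stress neuropeptides in male extreme 4 (0.71), immediate early genes in male control 1 (0.763), striatal markers in male extreme 2 (0.828), hypothalamic (0.752) and astrocyte markers (0.833) in male minimal 2, cortical markers in female minimal 4 (0.736), blood (0.78) and monoamine genes (0.712) in male control 5, interferon genes in male extreme 3 (0.733), antigen presentation in female minimal 2 (0.837), other neuropeptides in male extreme 2 (0.715) and sex steroid genes in female minimal 1 (0.782).

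Among genes, the only lower-state arrays of their groups were marked for the state probes: Rpl37l1 (0.81), Rpl7 (0.827) and Rpl23 (0.905) in female extreme 2, and Rpl37l1 (0.961), Rpl7 (0.891) and Rpl23 (0.927) in male minimal 1. Female extreme 2 was also marked for Snurf (0.824) and Bbs4 (0.77), and male minimal 1 for Nop58 (0.749) and Nr3c2 (0.763). Female minimal 4 was marked for Klf5 (0.777) and Cacng3 (0.834), male control 4 for Nfkbia (0.825), RT1-M3-1 (0.782) and Tssc4 (0.814), and female extreme 5 for Ndrg2 (0.833) and Nr3c2 (0.733). The rest were Nr3c2 in female minimal 5 (0.77), Zbtb18 in male extreme 1 (0.719), Apold1 in female control 2 (0.749), Hsp90b1 in female control 3 (0.794), Neurl2 in female control 5 (0.738), Sgca in male extreme 2 (0.759) and Ndufaf5 in male minimal 2 (0.713).

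Effects that differed between the sexes by the interaction were marked as well. For exposed minus control these were Agap2 (1.2), Gal3st3 (1.19), Zbtb18 (1.19), Gria3 (1.13), Agt (-1.82), Rpl37l1 (-3.47), Rpl7 (-2.89) and Rpl23 (-2.01). For extreme minus minimal they were Phospho2 (0.525), Poldip2 (0.495), Nfkbia (-1.4), Nfil3 (-1.14) and Apold1 (-0.901).

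The higher glucocorticoid-induced genes in extreme than in minimal females could stem from the array state or from tissue composition. Within the higher-state arrays the difference was 0.243 (4 against 3 rats), and with 3 regional scores as covariates it was 0.294, against 0.308 before. Neither the state nor these 3 scores thus accounted for most of it. Other aspects of composition were not adjusted for. The astrocyte mean, for 1, was 0.106 in minimal and -0.115 in extreme females, and the choroid plexus mean 0.215 and 0.455. Composition as a whole is therefore not excluded. With the rats paired by number the two-sided exact permutation p was 0.0625, the smallest that 5 pairs can give. A response related to behaviour remains possible, and the data may equally reflect what the rats met shortly before death, which was not tested.

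The 597 calls for the sex difference of exposed minus control could follow the array state, which ran in opposite directions in the sexes. Of these calls 75.7% had the sign that the state difference within groups predicts, against 56.2% of all probes, and 14 probes passed with the state as a covariate. The median size fell from 0.518 to 0.347 and the median SE rose from 0.129 to 0.169, so the calls ended both because effects shrank and because precision was lost. Under the thalamic, striatal and hypothalamic scores as covariates 603 probes passed, so these scores did not account for the count. Other aspects of composition were not adjusted for. The myelin list passed camera in this comparison (median -0.664; adjusted p = 0.00621; adjusted p = 0.885 with an estimated correlation). Composition as a whole is therefore not excluded. As the design ties state to group, a sex-specific response and the state cannot be told apart. Real groups gave the most calls in the regroupings (1 of 100 as large, the real one, with 11 as the highest other). This makes chance alone unlikely but does not exclude the state.

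The 2553 calls for male minus female may largely reflect how the tissue was cut. With 3 regional scores as covariates 114 probes passed, and the median size fell from 0.281 to 0.132 while the median SE went from 0.0728 to 0.082, so shrinking effects ended most calls. With the array state as a covariate 2442 passed. The share of higher-state arrays differed by only 0.13 between the sexes, so this covariate could change little and the count decides nothing. Of the calls 70.3% had the sign that the state difference within groups predicts, against 58.8% of all probes. Real groups gave the most calls (1 of 100 as large; highest other 1). A sex difference in the tissue itself would give the same pattern, and a dissection difference was not tested apart from it.

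For female extreme minus minimal the count of probes was as large as the real 17 in 8 of 100 regroupings, the highest other being 1347, so chance is not excluded for the count. A split that calls many more probes than the real groups points to structure among the samples, and of 16 regroupings that part every same-numbered pair 1 was as large (the real 17; highest other 1), too few for a share under 0.05.

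For the remaining comparisons, the number of 100 regroupings with as many calls was 1 for female exposed minus control (918; highest other 522), 1 for female extreme minus control (870; 654), 6 for female minimal minus control (264; 511), 1 for male extreme minus control (106; 4), 2 for exposed minus control over both sexes (102; 499), 4 for extreme minus minimal over both sexes (3; 87) and 2 for the sex difference of extreme minus minimal (7; 18). It was 100 by limma for male exposed minus control (0; 1), male extreme minus minimal (0; 1) and male minimal minus control (0; 59). For the correlation of male and female fold changes it was 2 for exposed (-0.383; highest other 0.384), 3 for extreme minus control (-0.404; 0.454), 35 for extreme minus minimal (-0.181; -0.448) and 20 for minimal minus control (-0.228; 0.435). Chance is therefore not excluded for the female minimal count and for the last 2 correlations. The shares of 4 or fewer of 100 were not adjusted for the number of such tests. Chance is less likely there but not excluded.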

How the results depend on the processing

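Values below were taken from fits with other settings than the reported one, and unless stated otherwise the cause of a difference was not tested. Of 523 named values, 511 kept direction and side of the threshold with no filter, 475 with array weights, 509 with robust variances and 518 with 1 probe per gene. Of 579 values 568 did so with the replicate number as a block, 501 with the array state, 456 with regional scores and 403 with both as covariates. Signal over background could not be judged without the scanner columns. For the same reason 3 settings chosen beforehand were not run: log2(signal + 16) without background correction, the stricter detection filter, and the BeadChip as a block.

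With no filter, male extreme minus control had 59 calls and the sex difference of extreme minus minimal 4, and the correlations of male with female fold changes were -0.339 (exposed) and -0.365 (extreme minus control). With array weights the counts were 10 for female extreme minus minimal, 428 for female minimal minus control, 193 for male exposed minus control, 201 for male extreme minus minimal, 362 for male extreme minus control, 2 for male minimal minus control, 312 and 7 for both sexes exposed and extreme minus minimal, and 1402 and 3 for the sex differences of exposed and of extreme minus minimal. With robust variances they were 44 for male extreme minus control, 0 by limma for both sexes extreme minus minimal and 3 for its sex difference. With 1 probe per gene, which tests fewer probes, they were 540, 519 and 150 for female exposed, extreme and minimal minus control, 48 for male extreme minus control, 63 and 5 for both sexes, and 309 and 4 for the sex differences. In fits of only the arrays of that sex they were 353 (female exposed), 7 (female extreme minus minimal), 329 (female extreme minus control), 70 (female minimal minus control), 53 (male exposed), 76 (male extreme minus minimal) and 350 (male extreme minus control).

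With the replicate number as a block, 4 lists passed in female exposed minus control; the blood, ribosomal and heat shock lists each went to 0.0566. In female extreme minus minimal the block gave 20 calls, and over the 10 exposed female arrays alone 2 with and 3 without the block. The block also moved Lxn (0.056) and Bhlhe40 (0.0499) in female minimal minus control, Klf4 (0.0477) in female extreme minus control and Ddit4 (0.0562) over both sexes by limma adjusted p, and changed no other named call than those printed here and in the report. With an estimated correlation 0 lists passed in female exposed minus control, 1 in female extreme minus minimal and 0 in male exposed minus control, and with fry 2, 1 and 0.

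With the array state as a covariate the counts were 26 for female extreme minus minimal, 0 by limma for male extreme minus control, and 14 and 1 for the sex differences of exposed and of extreme minus minimal; 6 lists passed in male exposed minus control and 2 in male extreme minus minimal, and the correlations were -0.613 (exposed), -0.327 (extreme minus minimal), -0.666 (extreme minus control) and -0.345 (minimal minus control). Error in the estimated state effect enters the sexes with opposite signs, which by itself pushes these correlations below 0. The state probes turned by construction: Rpl37l1 to -0.319, Rpl7 to -0.233 and Rpl23 to -0.0773 in female exposed minus control, Rpl37l1 to -0.335 and Rpl7 to -0.193 in female extreme minus control, Rpl37l1 to 0.0807 in male extreme minus control, and Rpl37l1 to 0.361, Rpl7 to 0.146 and Rpl23 to 0.0327 in the sex difference of exposed.

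With regional scores 3 lists passed in female exposed, 0 in male exposed minus control and 1 in male extreme minus minimal. The counts were 11 for female extreme minus minimal, 6 for male exposed and 291 for male extreme minus control, 170 for both sexes exposed, 114 for male minus female and 4 for the sex difference of extreme minus minimal, and the correlations -0.457 (extreme minus control) and -0.145 (minimal minus control). In male minus female Trh turned to 0.172, Crhbp to -0.024, Nrgn to -0.0606, Prkch to 0.0479 and Enpp6 to 0.0199.

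With both covariates the counts were 228, 153 and 116 for female exposed, extreme and minimal minus control, 0 by limma for male extreme minus control, 277 for both sexes exposed, 148 for male minus female, and 2 and 1 for the sex differences; 1 list passed in female exposed, 0 in male exposed minus control and 3 in male extreme minus minimal. The correlations, which carry the same error of the state effect, were -0.308 (exposed), -0.0245 (extreme minus minimal), -0.361 (extreme minus control) and -0.0753 (minimal minus control). Rpl37l1, Rpl7 and Rpl23 turned to -0.211, -0.17 and -0.061 in female exposed and to 0.185, 0.0698 and 0.0136 in the sex difference of exposed, and Rpl37l1 and Rpl7 to -0.164 and -0.0725 in female extreme minus control. Trh, Crhbp, Nrgn, Prkch and Enpp6 turned to 0.182, -0.0114, -0.041, 0.0528 and 0.0256 in male minus female.

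With the filter at the 60th percentile 3 lists passed in female exposed minus control, and the counts were 140 for female minimal minus control and 59 and 5 for both sexes exposed and extreme minus minimal. With the other background correction they were 40 for male extreme minus control, 0 by limma for both sexes extreme minus minimal and 3 for its sex difference. Within lower-state arrays, which are fewer, they were 328, 134 and 39 for female exposed, extreme and minimal minus control, 5 for female extreme minus minimal, and 0 by limma for both sexes extreme minus minimal and for its sex difference; the lone female extreme array was assumed to vary like the other groups. Rpl37l1, Rpl7 and Rpl23 turned to -0.303, -0.331 and -0.0963 in female exposed, and Rpl37l1 and Rpl7 to -0.171 and -0.292 in female extreme minus control. Within higher-state arrays 5 probes passed in female extreme minus minimal. With split controls the shared correlation of minimal and extreme was 0.39 in females (0.0607 to 0.571) and 0.198 in males (0.0313 to 0.332).

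Leaving out each array in turn gave 390 to 1179 calls for female exposed, 481 to 1005 for female extreme and 145 to 430 for female minimal minus control, 12 to 29 for female extreme minus minimal, 0 to 3, 3 to 111 and 0 to 1 for male exposed, extreme and minimal minus control, 0 to 51 for male extreme minus minimal (by limma), 26 to 141 and 2 to 14 for both sexes exposed and extreme minus minimal, 2159 to 2814 for male minus female, and 293 to 990 and 3 to 39 for the sex differences. Lists past the threshold numbered 2 to 8 (female exposed), 6 to 11 (female extreme minus minimal), 0 to 2 (male exposed) and 0 to 3 (male extreme minus minimal). The correlations between the sexes ran from -0.426 to -0.267 (exposed), -0.289 to 0.0204 (extreme minus minimal), -0.48 to -0.325 (extreme minus control) and -0.306 to -0.0965 (minimal minus control), and those between minimal and extreme from 0.661 to 0.784 in females and 0.29 to 0.583 in males.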

Other observations

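Several systems named in work on stress did not pass as lists in females. The monoamine list had a median of -0.0191 in exposed minus control (adjusted p = 0.713 by camera) and -0.00873 in extreme minus minimal (0.345), the neurotrophin and activity-secreted list 0.0544 (0.638) and -0.086 (0.293), the sex steroid list -0.0297 (0.975) and 0.00119 (0.945), and the chromatin and DNA methylation list 0.018 (0.713) and 0.0801 (0.293). Microglial markers were at -0.0615 (0.258) and -0.081 (0.307), and interferon genes at -0.0108 (0.861) and -0.0178 (0.333). Of the ionotropic glutamate receptor genes 1 rose and 2 fell in exposed females, with a list median of -0.127 (0.64).

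Some probes parted the arrays in other ways. The probes of Slc17a6, a thalamic marker, and Plvap were high in the same 8 female arrays, Pmch in 5, Prkcd in 7, Trh in 7, and the striatal markers Adora2a and Rgs9 in the same 9.

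The test in this paragraph was chosen after the pattern was seen. Both probes of the ribosomal protein gene Rps9 were high in 6 rats from 4 groups (female control 3 and 5, male control 1 and 4, male minimal 2 and male extreme 3), at 11.3 ± 0.37 against 7.349 ± 0.211 (SD, n = 6 and 24) and 12.34 ± 0.183 against 9.931 ± 0.394. A higher level of ribosomal transcripts would raise the others, but 57 other ribosomal genes, without the 3 that mark the array state, had a median difference of 0.014, from -0.15 to 0.17, which argues against it. An unnamed probe was high in the same 6 rats, with a gap of 3.27 between the arrays, against 2.92 and 1.51 for the Rps9 probes. Which gene it measures is not known here. The source of the pattern was not tested further.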
